A study of Arabidopsis thaliana with 18 samples.

How the data were processed

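Total RNA of Arabidopsis thaliana accession Est was labelled with biotin and hybridised to Affymetrix ATH1 arrays, 1 sample per array, per the labels. The 18 arrays fall into 2 treatments of 9, a 0.02% solution of the wetting agent silwet and 0.3 mM SA (salicylic acid, as the abbreviation is used in plant defence work) in the same solution, and the titles give each treatment the replicate numbers 1, 2 and 3, each used 3 times. The labels do not say what separates arrays that share a treatment and a number, nor whether they came from separate plants, so p-values measure the spread between these samples, which may be technical in part. Tissue and time of harvest are not given in the sources used here. The titles also carry a number from 37 to 54, and in that order each treatment runs through the replicate numbers 3 times. Such a series of 3 arrays is called a title run here: silwet 37 to 39, 40 to 42 and 43 to 45, and SA 46 to 48, 49 to 51 and 52 to 54.

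The deposited values are linear intensity signals, 1 per probe set, made with MAS5 per the submitters' processing notes, which name no version or settings. Every array had been scaled: after leaving out the lowest and highest 2% of probe sets, its mean signal lay between 100.008 and 100.01, and median signals ran from 27.4 to 35.7. Because MAS5 scales each array to one level, a change of total RNA would not be seen, and signals of dim probe sets are noisy. No further scaling was applied in the main setting. No 2 arrays held identical values, and each value column was matched to 1 sample.

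Of 22810 probe sets, 64 controls were left out, as were probe sets whose mean lay under the 25th percentile, and 17059 were tested. Values were analysed as log2(signal + 16), and a log2 difference on this scale understates changes of dim probe sets. Tests used limma 3.58.1 in R 4.3.3 (linear models, moderated variances with a trend) with Benjamini-Hochberg adjustment and a threshold of 0.05. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision.

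Gene names came from a table of the platform's annotation, updated through gene identifiers to the TAIR10.1 gene table. It lists 14016 probe sets, 13513 with 1 gene (13436 of them matched to a locus) and 503 with several, while 8730 other probe sets are not named here. Of the probe sets tested, 9498 had 1 gene and 7561 are unnamed, so many well-known SA marker genes are not analysed by name here.

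The main comparison set the 9 SA arrays against the 9 silwet arrays, and an F-test of the interaction asked whether the difference varied between replicate numbers. The named genes were to be those with adjusted p under 0.05 and the same sign in each replicate number, the 12 largest rises and 10 largest falls, with up to 4 passing members of each gene list or, where none passed, the 2 with the smallest p. This rule, the 21 gene lists (395 loci, 58 of them named on the array and 54 tested) and the main alternatives were fixed before the data were examined. The rule also included PR1, PR2, PR5 and ICS1 wherever measured, but none of these genes is analysed by name here. Lists with at least 3 tested members (9 lists) were tested with camera at a preset correlation of 0.01, with 1 probe set per locus, and again with an estimated correlation. The TGA factor, flower and seed lists had 0 members named on the array. The alternatives were offsets of 1 and 64, quantile normalization, no filter, a filter at the median, the replicate number as a block, arrays averaged within treatment and replicate number with that block (6 means), each replicate number left out, the title run as a random block, array weights, no variance trend, a Wilcoxon test and a 2-fold limit.

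Arrays with the same replicate number deviated together across treatments: the correlations of their mean deviations from the treatment means, across probe sets, were 0.757, 0.564 and 0.646 for numbers 1, 2 and 3. Each was higher than with any other number, which follows in part because the deviations within a treatment cancel out. The numbers of the titles may therefore pair the arrays, but the main fit and the fit of title runs did not use them as a block. Blocked values are given where they change a call or move a count by over 1.5 times.

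The comparison of title runs was chosen after seeing the data. The labels do not say which SA run belongs to which silwet run. The titles carry a further code that lies close together for arrays of the same position in both treatments, but the labels do not say what it means, and neither the run test nor its chance groupings used it. Each SA run was set against each of the 3 silwet runs in 1 limma fit. A probe set passed when it differed the same way from all 3, with the largest of the 3 p-values adjusted over all probe sets. Its difference is given as the smallest of the 3. Named genes follow the same numbers as above, ranked by this smallest difference. Differences between the runs of 1 treatment were tested with limma's F-test.

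The procedures were tested on simulated data with the real means of 17059 probe sets. The spread was that within treatments for the 9 against 9 arrays, the interaction and the list test. For the run test, the F-test between runs and the 6 means it was the spread within title runs. With 9 against 9 arrays, 94% of 100 probe sets changed by log2 1 and 99% of 100 changed by log2 2 were recovered, with 10 false calls. For 1 run against each of 3, the shares were 67% and 98% with 0 false calls. For the 6 means they were 96% and 100% with 10 false calls. The interaction test recovered 90% of 100 probe sets changed by log2 3 with 7 false calls, and the F-test between runs recovered 98% of 100 changed by log2 2 with 9 false calls. The list test found the 1 raised list of 6 genes with 0 false calls. These simulations assume independent errors and add no differences between title runs or replicate numbers beyond the changed probe sets. They therefore do not show how many false calls the 6 means give where runs differ.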

Results

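The series measured transcript levels in Arabidopsis accession Est after 0.02% silwet, a surfactant that helps a solution wet leaves, or 0.3 mM SA, the defence hormone salicylic acid, in the same surfactant. There were 9 silwet and 9 SA arrays, 3 per treatment and replicate number. Median signals of the arrays ran from 27.4 to 35.7. The series belongs to a project on expression level polymorphisms, which examined how Arabidopsis accessions differ in expression, and this part covers 1 accession.

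The named genes that differed most between SA and silwet arrays were PDF1.2 and PDF1.2b, plant defensins used as markers of the jasmonate and ethylene response, which were lower with SA, and UGT76B1, a glucosyltransferase that acts on salicylic acid and isoleucic acid, which was higher. Over all arrays none of these differences exceeded the spread within treatments. PDF1.2 (AT5G44420) had a level of 8.41 ± 1.85 with silwet and 7.11 ± 1.38 with SA (log2, SD, n = 9 each), a difference of -1.29 with a standard error of 0.68. Most of this came from silwet titles 40 to 42: in series of 3 successive titles its means were 7.11, 10.24 and 7.88 with silwet and 6.69, 6.87 and 7.78 with SA. Without titles 40 to 42 the differences of PDF1.2 and PDF1.2b were -0.38 and -0.31. Both read highest on the same arrays, silwet titles 40, 41 and 44 and SA title 53, so they may not be 2 independent signals. UGT76B1 (AT3G11340) had 6.71 ± 1.14 and 7.74 ± 2.37, a difference of 1.02 with a standard error of 0.77. The differences of PDF1.2b (AT2G26020) and AT2G43590, a chitinase family member, were -0.91 and -0.70. AT2G43590 was singled out after its values were seen.

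In the limma test of 9 against 9 arrays, 0 of 17059 probe sets rose and 0 fell (smallest adjusted p = 0.9998). At an unadjusted p under 0.05 there were 234, where 853 would be expected by chance, and the Wilcoxon test called 0, with 224 at that level. The 95% interval of the difference lay within 1 log2 unit of 0 for 16832 probe sets (98.7%), and its median half-width was 0.27. Differences between title runs of a treatment, found at 4185 probe sets within SA, stay in the spread of this fit. It can therefore miss changes limited to some runs, and 0 calls do not show that SA had no effect. Within replicate numbers 1, 2 and 3 alone the test of 3 against 3 arrays also called 0, with 99, 80 and 221 at an unadjusted p under 0.05. With the replicate block the count stayed 0 (281 at that level).

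Averaging the 3 arrays of each treatment and replicate number gave another result. In these 6 means, with the replicate number as a block, 15 probe sets rose and 17 fell with SA. Each mean pools the title runs of its treatment, so differences between runs stay in the treatment difference but not in the error. The standard errors and p-values of this fit therefore measure only the scatter between replicate numbers. All 32 had the same sign in each replicate number, which a test on 3 paired differences largely selects for. UGT76B1 rose by 1.02 with a standard error of 0.11, against 0.77 over all arrays (2.03-fold, limma adjusted p = 0.00152 in the means). AT2G37750 rose by 0.63 and AT3G13610, the feruloyl-CoA hydroxylase F6'H1 of scopoletin synthesis, by 0.49. PDF1.2 fell by 1.29 (2.45-fold, adjusted p = 0.00226) and PDF1.2b fell by 0.91 (1.87-fold). AT2G43590 fell by 0.70 and AT4G12490, a lipid transfer protein family member, also fell by 0.70. AT2G41190 fell by 0.58, AT1G52770 fell by 0.49, AT5G09570 fell by 0.48, AT3G24190 fell by 0.44, and psbB, the chloroplast gene of a photosystem II core antenna protein, fell by 0.46. The other 20 probe sets that passed are unnamed here.

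This count rests on 3 pairs of means: it was 1 without the arrays of titles 40, 43 and 52, where none of the 12 named genes passed, 3 without the filter on dim probe sets, 10 without the variance trend, and at least 32 in 10 of 99 other splits of the arrays. Without titles 40, 43 and 52 several differences stayed about as large, such as 0.91 for UGT76B1, 0.67 for AT2G37750, -0.93 for AT4G12490 and -0.61 for AT2G43590, while AT2G41190 and psbB had -0.23 and -0.15. Without titles 37 to 39 and 46 to 48 UGT76B1 no longer passed (difference 0.17), and AT3G13610 had a difference of -0.25. Without titles 40 to 42 the count was 1014, PDF1.2 no longer passed (difference -0.38, adjusted p = 0.104), and PDF1.2b had a difference of -0.31 (adjusted p = 0.0457). Without titles 40 to 42 and 49 to 51 the count was 817, and neither passed (differences -0.26 and -0.15). AT2G43590 had a difference of -0.33 (adjusted p = 0.178) in the first of these settings and turned to 0.0626 in the second.

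**Figure D1:**
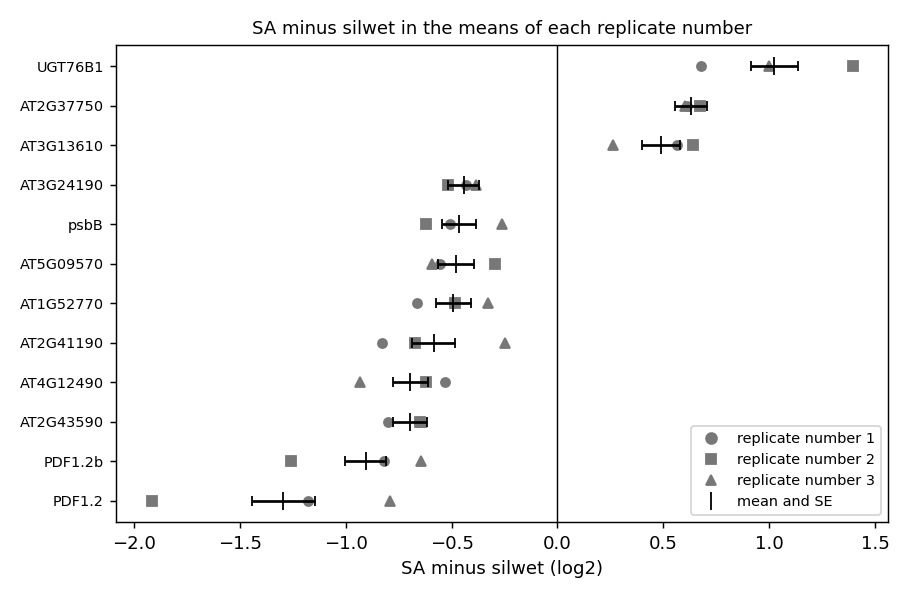
SA minus silwet (x axis, log2) for the 12 named genes that passed in the means of the replicate numbers (y axis), with 1 grey symbol per replicate number and a black bar for the mean and its standard error. All 3 differences of UGT76B1 lie above 0 (mean 1.02) and all 3 of PDF1.2 lie below 0 (mean -1.29).

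No fixed gene list changed between SA and silwet over all arrays. Of 4 tested members of the jasmonate and ethylene defence list, 0 passed, 3 were lower with SA, and the median difference was -0.50 (adjusted p = 0.208 in limma's camera test). Of 10 photosynthesis genes 0 passed and 9 were lower, with a median of -0.08 (camera adjusted p = 0.208). In the SA signalling list only 3 of 30 fixed loci could be tested, UGT76B1, GRX480 (difference 0.21) and SAG101. Of these 0 passed, with a camera adjusted p of 0.307. The jasmonate and ethylene list held 31 loci and the photosynthesis list 52, so each result covers a small part of its list. Adjusted over the list alone, 0 members of any list passed.

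In the 6 means these 3 lists passed. The jasmonate and ethylene list was lower with SA (2 of 4 fell, PDF1.2 and PDF1.2b; adjusted over the list alone also 2; adjusted p = 0.00159), and with an estimated correlation its adjusted p was 0.345. This call depended on silwet titles 40 to 42, without which its adjusted p was 0.182, and the other 2 members, JMT and THI2.1, had differences of -0.10 and 0.09. PDF1.2 and PDF1.2b read highest on the same arrays, so they may not count as 2 independent members. The SA signalling list was higher (1 of 3 rose, UGT76B1; adjusted over the list alone 2; adjusted p = 0.00159), and with an estimated correlation the adjusted p was 0.343. The photosynthesis list was lower (0 of 10 passed; adjusted over the list alone 2 fell; adjusted p = 0.00324), and with an estimated correlation the adjusted p was 0.343. Its members LHCB4.2, a light-harvesting protein, and PRK, phosphoribulokinase of the Calvin cycle, had differences of -0.20 and -0.16. The other 6 lists did not pass in the means, and the auxin, expansin, aliphatic glucosinolate and cold lists each had 1 member that passed when adjusted over the list alone. The photosynthesis list also passed over all arrays after quantile normalization (adjusted p = 0.00380, or 0.386 with an estimated correlation).

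The other lists with at least 3 tested members did not pass over all arrays. The camera adjusted p was 0.584 for the endoplasmic reticulum secretory genes and 0.564 for the detoxification, auxin, expansin, aliphatic glucosinolate and cold, drought and abscisic acid lists. The secretory genes passed as lower with SA with array weights (adjusted p = 0.00485) and without titles 37 to 39 and 46 to 48 (adjusted p = 3.28e-07). With an estimated correlation these adjusted p-values were 0.862 and 0.112. In the smaller lists 0 members passed: differences were 0.23 for WRKY53, 0.22 for WRKY6, 0.14 for BIK1, -0.07 for UGT74B1, 0.06 for DFR, -0.01 for UF3GT, -0.13 for HSP22, 0.11 for SAG29, -0.24 for CML38, 0.14 for ZAT10, -0.24 for GI and 0.02 for the root hair marker EXPA18.

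The difference between treatments did not vary detectably between replicate numbers. The limma F-test of the interaction called 0 probe sets, with 99 at an unadjusted p under 0.05, where 853 would be expected by chance. Differences between title runs stay in the spread of this fit too, so 0 calls do not show that the replicate numbers agreed. The replicate numbers themselves differed at 107 probe sets. Control probe sets of the arrays did not differ detectably between treatments: the log2 ratio of 3' to 5' signal was 0.13 ± 0.36 with silwet and 0.21 ± 0.32 with SA for GAPDH, 1.96 ± 0.34 and 2.04 ± 0.57 for actin, and 1.76 ± 0.26 and 1.70 ± 0.34 for ubiquitin (SD, n = 9; adjusted p = 0.915 in each of 4 two-sided exact permutation tests, which include the bioB spike signal).

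The SA arrays of titles 46 to 48 differed from all 3 silwet runs, with the SA signalling genes UGT76B1 and GRX480 and the transcription factor gene WRKY53 higher and 2 GDSL lipase family genes among those most lowered. These runs are the series of 3 successive titles in each treatment, a division chosen after seeing the data. UGT76B1 had a level of 10.67 ± 0.15 (log2, SD, n = 3) there, against 7.94 ± 0.26, 6.47 ± 1.07 and 5.72 ± 0.33 in the silwet runs 37 to 39, 40 to 42 and 43 to 45, so that it rose by at least 2.73 (6.63-fold, limma adjusted p = 0.00274). WRKY53, which acts in leaf senescence and defence, had 9.75 ± 0.03 against 8.26 ± 0.47, 7.03 ± 0.16 and 6.84 ± 0.25, and GRX480, a glutaredoxin that binds TGA factors, had 9.64 ± 0.22 against 8.36 ± 0.36, 7.84 ± 0.20 and 7.43 ± 0.11. Their smallest rises were 1.49 and 1.28. In the SA runs 49 to 51 and 52 to 54 UGT76B1 had levels of 7.13 ± 0.54 and 5.41 ± 0.73.

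**Figure D2:**
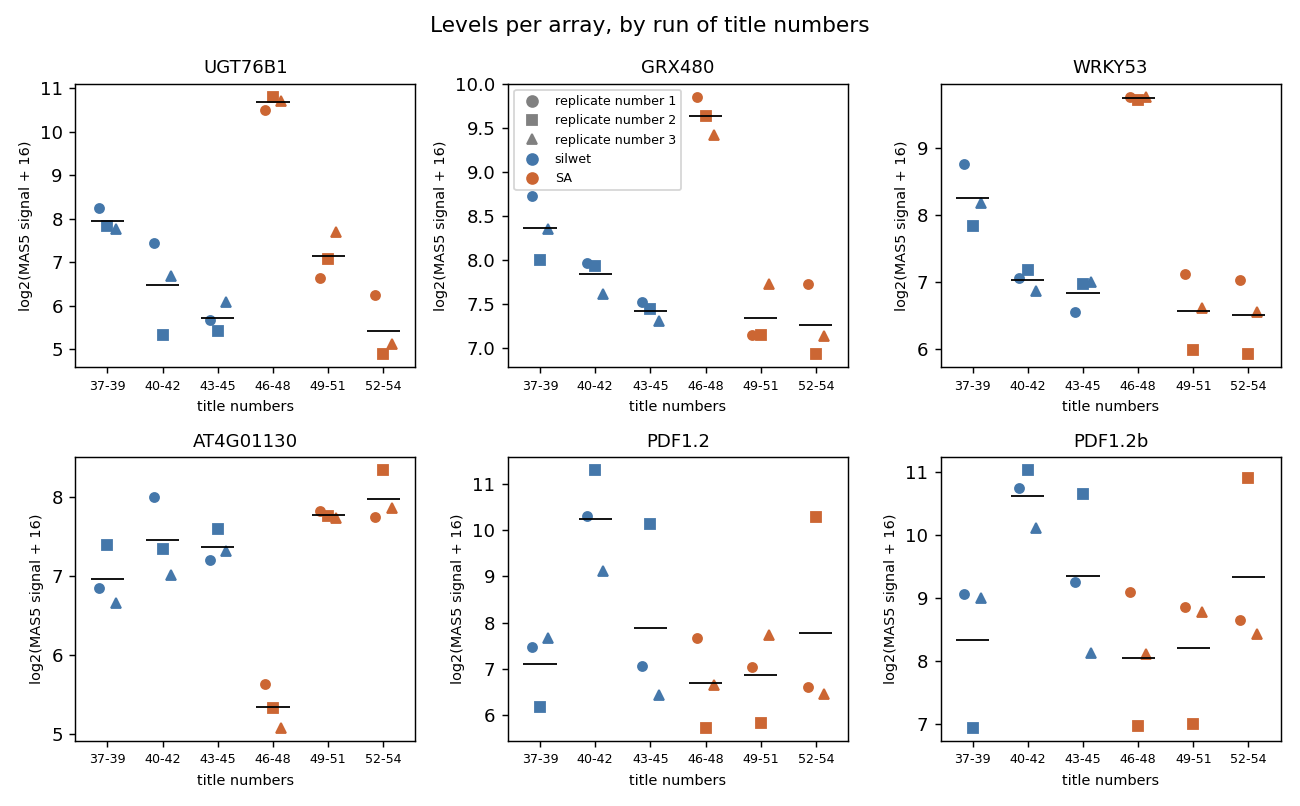
Levels per array (y axis, log2(MAS5 signal + 16)) of 6 genes by run of title numbers (x axis), silwet in blue and SA in orange, with 1 symbol per replicate number and a line for the mean of 3 arrays. UGT76B1, GRX480 and WRKY53 are highest and AT4G01130 is lowest in SA titles 46 to 48, while PDF1.2 has run means from 6.69 to 10.24.

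In all, 171 probe sets rose and 118 fell in SA titles 46 to 48 against each silwet run, 103 and 60 of them with 1 gene. The balance depended on the offset, with 120 up and 146 down at an offset of 1 and only 93 of 378 down at 64. After UGT76B1, the largest smallest rises were those of AT4G01870 (1.85), AT3G13610 (1.82), AT1G08050 (1.79), AT4G22530 (1.75), AT4G32870 (1.67), AT5G62770 (1.66), AT1G02360, a chitinase family member (1.65), AT3G28510 (1.64), IAGLU, a glucosyltransferase of indole-3-acetate (1.61), and AT2G39210 (1.55). AT4G22530 had a level of 9.30 ± 0.24 against 7.55 ± 0.06, 6.47 ± 0.11 and 6.19 ± 0.26 in the silwet runs. Among the falls, AT4G01130 and AT1G29660, members of the GDSL lipase family, fell by 1.62 and fell by 1.58. AT3G20820, a leucine-rich repeat protein, fell by 1.48, and AT5G62360, of the invertase and pectin methylesterase inhibitor family, fell by 1.35. The falls of AT3G15570, AT1G78020, AT5G01790, AT5G62140, AT3G19000 and AT1G78995 were -1.33, -1.30, -1.27, -1.20, -1.19 and -1.15. PRK fell by 0.57.

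With the replicate block 699 probe sets passed, including all 289 of the unblocked test, and with the mean 3' to 5' ratio of the control probe sets as a covariate 112 rose and 66 fell. With 2 arrays per run, 415 passed without replicate 1, 2 without replicate 2 (none of the 24 named genes) and 10 without replicate 3 (3 of the 24). A lost call need not mean a lost difference: without replicate 2, UGT76B1 still read 10.51 and 10.70 in SA titles 46 and 48. In the silwet arrays left it read at most 8.25.

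**Figure D3:**
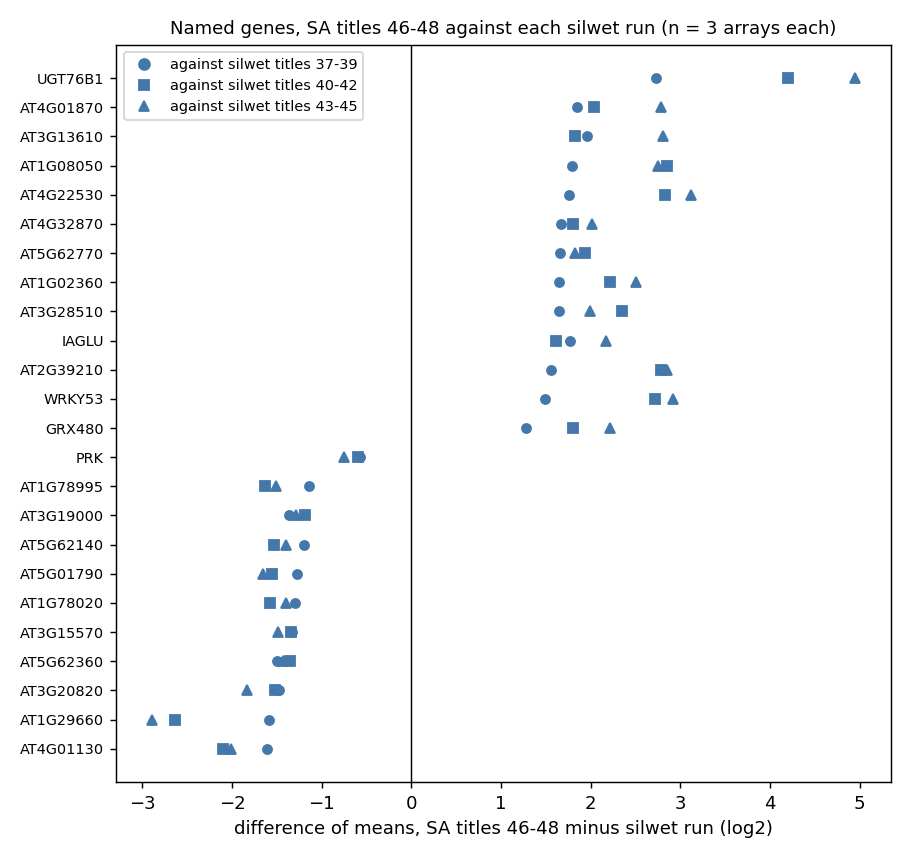
Difference of means (x axis, log2) between SA titles 46 to 48 and each of the 3 silwet runs for the 24 named genes (y axis), 1 symbol per silwet run, n = 3 arrays in each run. All 3 differences share a sign for every gene shown, as the test requires, and the smallest for UGT76B1 is 2.73.

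Of the fixed lists, 2 shifted in SA titles 46 to 48. In the SA signalling list 2 of 3 tested members rose, UGT76B1 and GRX480 (adjusted over the list alone also 2), and SAG101 did not pass (camera adjusted p = 0.000359). With an estimated correlation the adjusted p was 0.0845, and 0.0330 without titles 40, 43 and 52. The list of endoplasmic reticulum secretory genes, which serve protein folding and export, was higher (camera adjusted p = 0.000718), although 0 of its 6 members passed over all probe sets and 2, ERDJ3B and SEC61A2, passed when adjusted over the list alone and with the block. With an estimated correlation its adjusted p was 0.344. The smallest differences were 0.84 for the chaperone partner ERDJ3B, 0.75 for SEC61A2, a subunit of the translocon, and 0.41 for the transcription factor BZIP60. WRKY53 rose and WRKY6 did not pass.

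Other lists held single passing members or none. In the aliphatic glucosinolate list 0 of 3 passed over all probe sets and all 3 fell when adjusted over the list alone, with smallest differences of -1.14 for AOP3, -0.85 for UGT74C1 and -0.55 for BCAT4 (camera adjusted p = 0.0657), and 1 fell with the block. The list passed without the filter, without replicate 3 and without titles 40, 43 and 52 (camera adjusted p = 0.0377, 0.0290 and 0.0458), and with an estimated correlation these adjusted p-values were 0.379, 0.267 and 0.448. Of 6 detoxification genes 0 passed over all probe sets, and 3 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.083). The list passed with array weights (0.0406) and without replicate 3 (0.0478), and with an estimated correlation these adjusted p-values were 0.269 and 0.267. Of 10 photosynthesis genes 1 fell, PRK, and of 4 jasmonate and ethylene genes 0 passed (camera adjusted p = 0.244 and 0.851). Of 4 cold, drought and abscisic acid genes 0 passed (COR15B fell when adjusted over the list alone and with the block; camera adjusted p = 0.241). Of 3 auxin genes 0 passed and 1 rose when adjusted over the list alone (camera adjusted p = 0.241), and of 3 expansins 0 passed either way.

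Neither of the other SA runs had a probe set that differed from each silwet run. For titles 49 to 51 limma called 0, with 202 at an unadjusted p under 0.05, and for titles 52 to 54 it called 0, with 97, and a Wilcoxon test of 3 against 3 arrays was not run. The secretory genes were lower in both, with camera adjusted p of 0.00233 and 0.0226 and median smallest differences of -0.30 and -0.27, while 0 of 6 members passed. With an estimated correlation the adjusted p was 0.767 and 0.92. ERDJ3B had levels of 8.93 ± 0.29 and 8.99 ± 0.46 in these runs and 10.56 ± 0.11 in SA titles 46 to 48, against 9.61 ± 0.41, 9.63 ± 0.20 and 9.72 ± 0.14 in the silwet runs (SD, n = 3).

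Title runs of one treatment also differed from each other. Within SA 4185 probe sets differed between the 3 runs (5347 with the replicate block), and within silwet 271 did (785 with the block). Taken 2 at a time, SA titles 46 to 48 differed from silwet titles 37 to 39 at 516 probe sets (268 higher, 248 lower), from 40 to 42 at 3210 and from 43 to 45 at 2948. SA titles 49 to 51 and 52 to 54 differed from silwet titles 37 to 39 at 673 and 1033 probe sets and from the later silwet runs at 0, with 705 to 1159 at an unadjusted p under 0.05. The first component of the arrays' deviations from their treatment means held 41.2% of the variance and the second 16.7%.

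**Figure D4:**
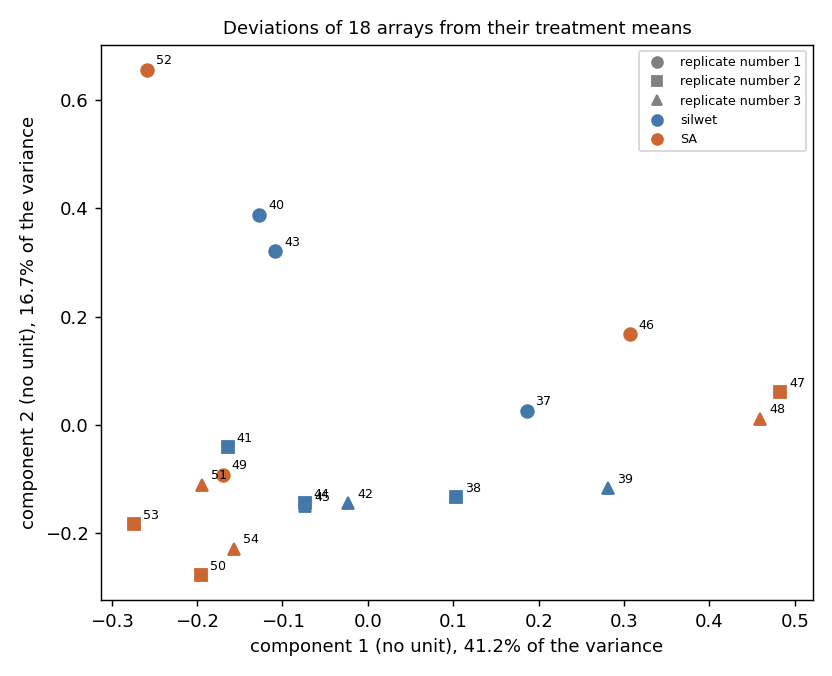
First (x axis) and second (y axis) component of the deviations of the 18 arrays from their treatment means over 17059 probe sets, without unit, marked by title number, treatment (colour) and replicate number (symbol). SA titles 46 to 48 lie between 0.31 and 0.48 and silwet titles 37 to 39 between 0.10 and 0.28 on the first component, and all other arrays lie below 0.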

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

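The comparison of title runs and its tests against the signal distribution, RNA quality and a state shared with silwet titles 37 to 39 were set up after the runs had been seen to differ, and the tests of replicate number 1, of the cold and drought genes and of the groupings of all 18 arrays for differences within a treatment were chosen after the results they measure were seen.

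Over 65 measures in each treatment, 11 of 130 groups of 9 arrays had 1 array far from the others, and chance gives this in about 1 in 20 groups. PDF1.2 read 10.29 on SA title 53, where the next highest SA array read 7.73. GSTU25 read 5.44 on SA title 47 (next 4.69), BIK1 read 8.25 on silwet title 39 (next 7.20), GH3.5 read 7.67 on SA title 46 (next 6.63) and AT3G19000 read 7.07 on silwet title 38 (next 6.70). The clock gene GI read lowest on silwet title 41, at 7.41, where the next was 8.21. AT2G41190 read 8.76 on SA title 52 (next 6.68). The median signal was lowest on silwet title 41, at 27.4 (next 32.3), the actin log2 ratio of 3' to 5' signal was 2.68 on silwet title 45 (next 2.07), and the bioB spike read 130.3 on silwet title 42 (next 84.4).

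The second component of the arrays was 0.656 on SA title 52 (next SA array 0.168), and silwet titles 40 and 43, the next highest of all arrays, had 0.388 and 0.321. All 3 carry replicate number 1, and a batch of that number stays open: its array was the highest of its run in all 6 runs, and in 3 of 3 runs without these titles. Of the 4 tested cold, drought and abscisic acid genes, 3 read higher on each of these arrays than on the other 15, but 1, LTI30, was among the 5% of probe sets best correlated with the component. RNA degradation also stays open: the component and the mean 3' to 5' ratio had r = 0.176 over 18 arrays (permutation p = 0.491), rho = -0.0609 (p = 0.811), and r = 0.0306 without the 2 farthest arrays, 1 relation being computed. The design names no biological difference between these arrays, and degradation and a cold or drought response cannot be told apart from others with 4 list members and 18 arrays.

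The differences of SA titles 46 to 48 from each silwet run (289 probe sets) exceed those of random groupings. Of 100 groupings of the arrays into 6 sets of 3, 1 gave as many, the real one, and the highest other gave 1. These groupings kept 1 array of each replicate number per set but not the pairs of title codes. They break up the title runs, so they show that arrays of a run belong together and not what set titles 46 to 48 apart. The tables argue against the distribution of signals as the cause of the differences, since 297 passed after quantile normalization. They also argue against a state wholly shared with silwet titles 37 to 39, since limma called 516 probe sets between these runs. The 99 other groupings, of which the highest gave 3, add nothing to this, as they break up the runs. SA titles 49 to 51 and 52 to 54 differed from silwet titles 37 to 39 at 673 and 1033. RNA degradation stays open in part, since 178 passed with the 3' to 5' ratio as a covariate. Yet the ubiquitin log2 ratios of titles 46 to 48 were 1.48, 1.43 and 1.27, where the other SA arrays had at least 1.55. Silwet titles 37 to 39 had 1.68, 1.62 and 1.27. Single readings went the other way: actin on title 47 (2.52) and GAPDH on title 46 (0.2996). For these, silwet titles 37 to 39 had at most 2.07 and 0.119. A higher ratio on titles 46 to 48 as a set was thus not seen. An SA response limited to titles 46 to 48 may account for the differences. However, the labels give no harvest time or other factor that sets this run apart. An unlabelled condition cannot be told apart from such a response.

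For SA against silwet over all arrays, where 0 probe sets passed in limma (234 at an unadjusted p under 0.05; Wilcoxon 0), and for the interaction, also 0 in limma (99 at that level), every split reaches a count of at least 0 (100 of 100 in both), so the splits say nothing about chance; the highest other counts were 0 and 24. The 32 probe sets that passed in the means of the replicate numbers came from an alternative chosen before the data were examined. The splits did not show them to exceed chance: 11 of 100 gave as many, the real one included, and the highest other gave 2400. Splits that call so many point to a structure of the samples, and in that split all 6 arrays of titles 37 to 39 and 46 to 48 were on 1 side. Of the 10 other splits with at least 32, 6 had 5 or 6 of these arrays on 1 side, as did 13 of all 100 splits. The real grouping has titles 37 to 39 and 46 to 48 on opposite sides. These splits therefore cannot decide whether the 32 arose by chance. For the differences between runs within SA (4185), 1 of 100 groupings of all 18 arrays gave as many, the real one, and the highest other gave 1. These groupings mix the treatments and break up the runs, so they show only that arrays of a run belong together. Within silwet (271) these groupings do not exclude chance, with 5 of 100 and a highest other of 3446, but they can place SA arrays in the silwet sets. Of the 36 groupings within a treatment, which were chosen first, 3 gave as many for SA (highest other 5014), so they do not exclude chance there. For silwet 1 did (highest other 247). In SA the 4 groupings that keep titles 46 to 48 together gave 4029 to 5014, and the other 32 at most 72. The SA count thus follows titles 46 to 48 and does not speak for the division of the other SA arrays. In silwet the 4 that keep titles 37 to 39 together gave 204 to 271, and the other 32 at most 1.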

How the results depend on the processing

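All alternatives for title runs and for named or counted results in the means, and those that leave out titles, block by title pairs or estimate correlations in a changed setting, were chosen after seeing the data. For SA against silwet the count was 0 in every other setting, 1 without the filter (0 up, 1 down) and 32 in the means of the replicate numbers. The replicate block left it at 0. Of the gene lists, 1 passed after quantile normalization, 1 with array weights (secretory genes, lower with SA, adjusted p = 0.00485), 3 in the means, and 2 without titles 37 to 39 and 46 to 48, where the aliphatic glucosinolates turned to higher with SA (adjusted p = 0.00333, or 0.250 with an estimated correlation), and 3 without titles 43 to 45 and 52 to 54. In the means 2 lists passed without titles 40 to 42, with or without titles 49 to 51 left out too, 5 without titles 43 to 45 and 52 to 54, and 3 without titles 37 to 39 and 46 to 48, the aliphatic glucosinolates again higher (adjusted p = 0.000244). None of these passed with an estimated correlation. The interaction count stayed 0 in all settings run. The title run as a random block was not run for the lists.

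In the means the 32 became 16 with an offset of 1, 3 without the filter, 17 with a filter at the median, 10 without the variance trend, 21 to 201 without 1 replicate, 1 without titles 40, 43 and 52, and 73 without titles 37 to 39 and 46 to 48, where AT3G13610 had -0.25. They became 1014 without titles 40 to 42, 817 without 40 to 42 and 49 to 51, where AT2G43590 had 0.0626, and 15 without 43 to 45 and 52 to 54. For SA titles 46 to 48 the 289 became 699 with the replicate block, 2 to 415 without 1 replicate, 1054 with array weights, 116 at a 2-fold limit, 266 with an offset of 1 (120 up, 146 down), 378 with 64 (93 down), 493 without titles 40, 43 and 52 (274 shared) and 178 with the 3' to 5' ratio. Differences within SA (4185) ranged from 1418 to 4078 without 1 replicate. Within silwet 271 became 785 with the block, 684 with array weights and 0 to 165 without 1 replicate. Of the lists for titles 46 to 48, 2 passed, 2 to 4 without 1 replicate, 3 without the filter, with array weights or without titles 40, 43 and 52 and 0 with an estimated correlation. With an estimated correlation in the settings with further lists, only the SA signalling list passed, without titles 40, 43 and 52 (0.0330). Leaving out a replicate leaves 2 arrays per run; the cause of the other changes was not tested.

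Values of the named genes of titles 46 to 48 kept direction and call in most settings: 240 were kept and 48 lost their call. In the means the calls were less stable: 89 were kept, 77 lost their call and 2 were reversed. Of 963 uncalled values 101 changed sign. Apart from the calls named in the report, the block changed no other call. Signal over background limits dim probe sets, whose log2 differences the offset shrinks.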

Other observations

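The values in the first paragraph were chosen for a component that had been seen, and the test of title pairs was chosen after the result was seen.

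Of the 12 named genes with the strongest part in the second component, which were picked for it, 11 read higher on each of silwet titles 40 and 43 and SA title 52 than on the other 15 arrays, and 7 of these 11 genes are given here with the exception, JAL23. AT3G28270 read 8.22, 7.74 and 9.05 there (log2), where the other 15 arrays ran from 4.03 to 5.13. AT3G28220 read 9.72, 9.71 and 10.51 against at most 8.74, and AT1G54020 read 7.51, 7.38 and 8.96 against at most 6.56. AT4G33550 read 8.11, 7.89 and 7.77 against at most 6.53, and AT1G16850 read 9.37, 8.03 and 8.27 against at most 6.91. LTI30, a dehydrin, read 11.28, 10.65 and 10.88 against at most 10.19, and HIS1-3, a linker histone, read 8.29, 7.82 and 7.83 against at most 7.08. JAL23 read 7.37, 8.10 and 8.67, while another array read 7.52. No enrichment of any group among these genes was tested, and of the fixed cold, drought and abscisic acid list 1 of 4 tested members, LTI30, was among the 5% of probe sets best correlated with the component. Of the others, COR47 read 11.06, 11.16 and 11.22 against at most 10.56, COR15A also read highest on these arrays, and COR15B read 11.06, 10.52 and 10.79, while another array read 10.95.

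Each SA title follows the silwet title of the same position and replicate number by a nearby code in the titles. The deviations of such arrays from their treatment means correlated across probe sets at 0.593, 0.339 and 0.677 for silwet titles 37 to 39 with SA titles 46 to 48, at 0.0969, 0.106 and 0.315 for the next 3 pairs, and at 0.575, 0.405 and 0.529 for the last 3. The mean of the 9 pairs, 0.404, lay among the highest of the 216 pairings within replicate numbers (exact one-sided p = 0.0231; mean over all pairings 0.151, highest 0.453). Arrays with neighbouring codes may therefore be matched samples, a hypothesis found and tested on the same data. With these pairs as a block limma called 0 probe sets in SA against silwet, with 498 at an unadjusted p under 0.05, and a Wilcoxon test without pairs also called 0.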
